A study of Homo sapiens with 6 samples.

How the data were processed

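RNA was sequenced from PLC/PRF/5 cells, an established line of human liver cancer, 48 h after transfection with SLU7 siRNAs or with the control siRNA siGL2, 3 libraries each. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from polyA RNA with a ScriptSeq mRNA-Seq kit. FastQC 0.11.8, Trimmomatic 0.38, kallisto 0.46.1 and sleuth 0.30.0 are named, with the build GRCh38, per the submitters' processing notes, which give no role or order for them. The estimated counts per transcript were made by the authors with a quantifier that splits reads between transcripts, per the file headers, and are neither normalized nor whole numbers. The TPM values were made by the authors from those counts and the effective length of each transcript, per the file headers. The GENCODE release of the transcripts, the strand setting and the use of bootstraps are not given in the sources used here. Without a strand setting, reads of overlapping and antisense genes such as ZFAS1 and SNHG15 cannot be told apart, and without bootstraps the uncertainty of splitting reads between similar transcripts was not modelled. Genes with near-identical copies, among them histone and HLA genes, CBWD6, POLR2J3, and HNRNPA1 and RPS14 with their pseudogenes, are uncertain for the same reason.

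Each file held 234485 transcripts. The 159 records of the pseudoautosomal regions on chromosome Y were added to those on X, and estimated counts were rounded to whole numbers and summed to 60607 genes. The libraries held 8693977, 7769866 and 7736584 (controls) and 6315740, 5191452 and 5361032 (knockdowns) estimated counts, with between 28741 and 31694 genes detected. Mitochondrial ribosomal RNA and 7SL RNA took a large share of the counts although the labels give polyA RNA. Gene symbols and transcript types were those in the files. Coordinates came from GENCODE 29 (GRCh38), which covered 97.5% of the tested genes.

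Genes, transcripts, and transcript usage were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (a count of 10 in a library at the size of the smallest group and 15 over all libraries), a quasi-likelihood test of knockdown against control over all 6 libraries, and Benjamini-Hochberg adjustment at 0.05. This left 17109 genes and 43128 transcripts. Transcript usage was tested with diffSpliceDGE and the Simes method in 8869 genes with at least 2 tested transcripts. Transcript class usage was tested with the same tool on counts summed per gene into protein-coding, retained-intron, nonsense-mediated decay and other transcripts, in 6680 genes with at least 2 classes. The share of each class per library was compared with an exact permutation test, for which 3 against 3 gives 0.1 as the smallest p.

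Gene lists written before the data were examined, 31 in number, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the lists. They covered splicing (SR proteins and TRA2, hnRNP proteins, the core spliceosome, second step factors), nonsense-mediated decay factors and targets, small nucleolar RNA hosts and ribosomal proteins. Others covered histones, mitosis, replication, cohesion, recombination and R-loops, DNA methylation, the DNA damage response, apoptosis, stress responses, lipid synthesis, hypoxia, inflammation, interferon, antigen presentation, TGF-beta, WNT, hepatocyte and fetal liver genes, mitochondrially encoded genes, and markers of immune cells, fibroblasts and endothelial cells. Transcript types were tested the same way on transcripts. A correlation estimated from the data and the rotation test fry were alternatives. Genes were named by a rule set before the data were examined: SLU7, the 12 largest rises and falls among protein-coding genes past the test with a mean of at least 5 CPM and no overlap between the groups, up to 4 members per list with the smallest p past the test (2 if none), and 10 preset genes. For transcript usage the 10 genes with the smallest p were named, and for the retained-intron and decay classes the 8 higher and 4 lower genes with the smallest p and at least 3 CPM in the class. Members beyond that rule, namely SNHG5, CYP51A1, SLC2A1, CCL20, HNRNPA1, TGFBI, COL1A2, CSF1R, CD68 and LYZ, were named after their values were seen. Some genes that the rule names are not reported here.

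The alternatives set before the data were examined were RLE size factors, no filter, a stricter filter (at least 1 CPM on average and a count of 10 in 3 libraries), the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma on log2(TPM + 1), glmTreat against a 1.5-fold change, offsets for average transcript length, the gene-level usage test, and limma diffSplice. Chosen after seeing the data were fits without control replicate 1 and knockdown replicate 3, with 1 surrogate variable (sva 3.50.0), without structural RNA and mitochondrial genes (281 of the tested genes), and with offsets from a smooth of GC content and length (mgcv 1.9.3, 97.6% of tested genes), and for class shares TPM with the effective length of each transcript averaged over the libraries. Fold changes on log2(TPM + 1) understate the change of low genes. Random steps used seed 1.

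The gene, transcript, transcript usage and class usage tests were tried on simulated libraries with the means and sizes of the real ones. These held 50 changed features at each of 4 fold sizes. Camera was tried only on gene lists, with a shift of 1.5-fold. Fry, camera on transcript types and the exact permutation test were not tried. For genes edgeR recovered 0, 14, 37 and 48 of 50 at 1.5-, 2-, 4- and 16-fold, with 9 false of 108 calls, and DESeq2 1, 25, 39 and 49, with 27 false of 141. For class usage limma recovered 0, 1, 10 and 35, with 0 false of 46 calls on retained-intron classes. A list of 20 genes shifted 1.5-fold had an adjusted p of 2.39e-08 with the preset correlation and 0.0795 with an estimated one, and 0 of the other lists among the 31 were called. Genes, transcripts and classes were drawn independently of each other, so the list simulation cannot show how the preset correlation does where genes move together. Nor do the false calls of any simulation include errors from splitting reads between transcripts or from libraries that stand apart. The camera simulation was redrawn and the 16-fold size added after a first run of it.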

Results

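PLC/PRF/5, an established human hepatocellular carcinoma cell line, was transfected with siRNAs against the splicing factor SLU7 or with siGL2, an irrelevant siRNA that served as negative control. SLU7 acts in the second catalytic step of pre-mRNA splicing, in which the exons are joined. RNA taken 48 h after transfection was sequenced from 3 knockdown and 3 control libraries, and transcripts were quantified. The title of the series places the question in whether less SLU7 changes which mRNA transcripts the cells make. The control libraries held 8693977, 7769866 and 7736584 estimated counts and the knockdown libraries 6315740, 5191452 and 5361032. Every control thus held more counts assigned to transcripts than every knockdown. Mitochondrial ribosomal RNA took 22.5%, 16.8% and 24.1% of the counts in the controls and 35.3%, 30.1% and 29.9% in the knockdowns. 7SL RNA, the RNA of the signal recognition particle, took 16.5%, 23.5% and 15.8% in the controls and 8.09%, 10.6% and 9.79% in the knockdowns. Control replicate 1 and knockdown replicate 3 stood apart from the other libraries of their groups, with deviations that correlated across genes (r = 0.44). Nothing in the labels says more of the replicates than that they are triplicates, so p-values measure only the spread between these samples, which may be technical.

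SLU7 mRNA was halved in the knockdown. The gene (ENSG00000164609.10, chromosome 5, 160401641 to 160421711 on the minus strand, GRCh38) fell from 18.7 ± 1.87 CPM in the controls to 9.31 ± 1.08 CPM in the knockdowns (SD, n = 3 each), 49.9% of the control level. In the edgeR quasi-likelihood test its log2 fold change was -1.002 (SE 0.18, Benjamini-Hochberg adjusted p = 0.0139), and no knockdown value reached the lowest control value. The full-length coding transcript SLU7-201 carried most of the signal, with 151.2, 111.1 and 116.1 estimated counts in the controls and 46.2, 30.7 and 44.4 in the knockdowns. The short retained-intron transcript ENST00000521190.5 held 7.8, 15.8 and 26.3 counts in the controls and 6.4, 6 and 5 in the knockdowns. Without knockdown replicate 1 or 2 the adjusted p was 0.0556 or 0.0805, at log2 fold changes of -1.005 and -0.92. With offsets for transcript length the change was -0.57 (adjusted p = 0.152), and on log2(TPM + 1) it was -0.063 (limma adjusted p = 0.868) where the median gene moved by 0.35, which leaves -0.41 relative to that shift.

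**Figure D1:**
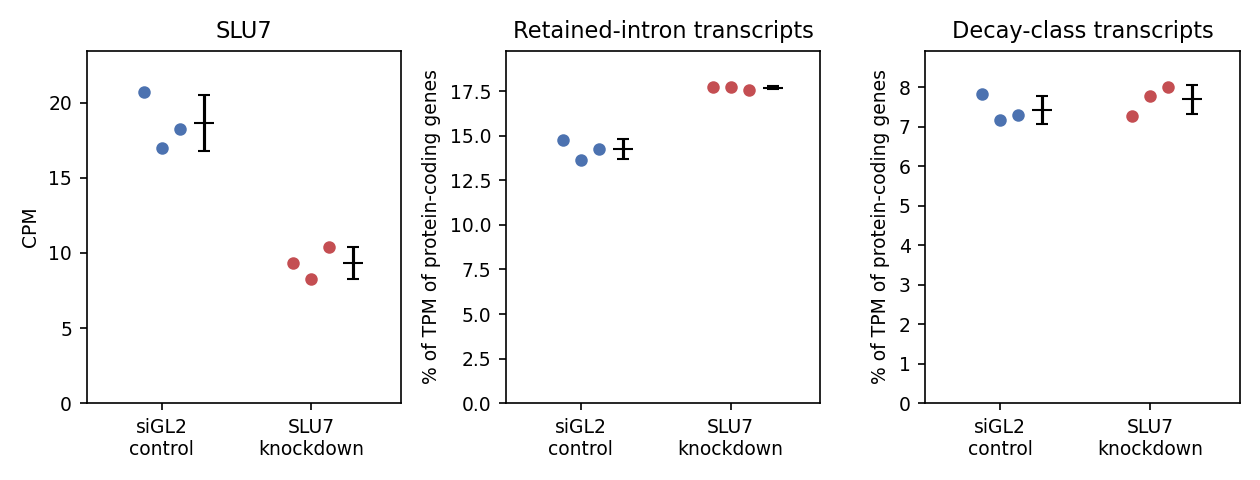
SLU7 expression in CPM (left) and the shares of the TPM of protein-coding genes held by retained-intron transcripts (middle) and by transcripts annotated for nonsense-mediated decay (right), in percent, with points for libraries and black bars for the mean and SD of 3. SLU7 averaged 18.7 CPM in controls and 9.31 CPM in knockdowns, the retained-intron share 14.2% and 17.7%, and the decay share 7.43% and 7.69%.

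With SLU7 knocked down, IL12RB2, CXCL5 and NOP56 were among the genes that rose most, and NOTCH3 and IGFBP1 among those that fell most. CXCL5, a neutrophil chemokine, rose from 1.99 ± 0.73 to 9.07 ± 1.64 CPM (log2 fold change 2.17, SE 0.32, adjusted p = 0.00947). IL12RB2, a chain of the interleukin-12 receptor, rose from 1.29 ± 0.25 to 8.95 ± 0.36 CPM (2.79, SE 0.27). NOP56, a core protein of box C/D small nucleolar ribonucleoproteins, rose from 66.6 ± 8.71 to 257.5 ± 78.4 CPM (1.95, SE 0.23). NOTCH3, a Notch receptor, fell from 46.4 ± 13.4 to 7.37 ± 1.14 CPM (-2.66, SE 0.26, adjusted p = 0.00631). IGFBP1, an insulin-like growth factor binding protein secreted by hepatocytes, fell from 1465 ± 472 to 291.2 ± 47.2 CPM (-2.33, SE 0.27, adjusted p = 0.00787). PLK4, the kinase that starts centriole duplication, rose 3.22-fold and RAE1, an mRNA export factor, 3.201-fold. LTV1, an assembly factor of the small ribosomal subunit, and ALKBH3, a nucleic acid demethylase, rose 3.19-fold. PDRG1, C22orf39 and PITHD1 rose by log2 fold changes of 1.93, 1.91 and 1.79. CBWD6 rose by 1.82 (adjusted p = 0.0491), but it has near-identical paralogs between which reads can be split, so its value is uncertain.

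Among the strongest falls was ZFP36, which directs the decay of mRNAs with AU-rich elements, from 26.7 ± 15.4 to 4.87 ± 0.21 CPM (log2 fold change -2.45, SE 0.42). CHAC1, a glutathione-degrading enzyme of the stress response, fell from 9.49 ± 4.57 to 2.04 ± 0.64 CPM. IL10RB, a chain of the interleukin-10 receptor, fell from 11.7 ± 2.62 to 2.72 ± 1.93 CPM and BHLHA15, a transcription factor of secretory cells, from 14.8 ± 3.30 to 3.57 ± 0.85 CPM. LGI4, MICALL2, AGAP2 and JPH3 fell by log2 fold changes of -2.49, -2.14, -2.12 and -2.10. The histone genes H2BU1 and H3C4 were at -2.72 and -2.02, again among close copies. Of the genes set for reporting whatever they did, UPF1, the central helicase of nonsense-mediated decay, rose from 45.3 ± 2.57 to 72.4 ± 3.18 CPM (0.68, SE 0.13, adjusted p = 0.0173). CDCA5, the cohesion factor sororin, rose from 12.02 ± 4.37 to 23.6 ± 2.04 CPM (0.97, SE 0.27, adjusted p = 0.0457). SRSF3 (0.51, adjusted p = 0.0856), HNF4A (-0.50, adjusted p = 0.0854), AQR (0.41), MKI67 (0.39) and DNMT1 (-0.15) did not pass the test, nor did ALB (0.19), which was at -0.027 with GC content offsets. DNMT1 had the other sign, 0.051, without the 2 libraries that stood apart. AFP was too low to test, with 9, 8 and 5 counts in the controls and 9, 3 and 5 in the knockdowns.

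In all, 17109 genes were tested and 2374 passed, 1015 higher and 1359 lower in the knockdown (edgeR, Benjamini-Hochberg adjusted p under 0.05), of which 443 were at least 2-fold higher and 711 at least 2-fold lower. The 3 values of each group did not overlap in 6270 genes, 36.6% of those tested, where chance gives 10%. Coding genes leaned downwards, with 782 higher and 1241 lower. Genes without a coding transcript whose most frequent transcript type was long non-coding RNA leaned upwards, with 151 higher and 73 lower. The count rested on single libraries: it was 4455 without control replicate 1, 456 and 624 without control replicates 2 and 3, and 337, 0 and 1043 without knockdown replicates 1, 2 and 3, so that every call on the expression of a single gene in this and the other paragraphs was lost without knockdown replicate 2. Without the 2 libraries that stood apart 5247 genes passed, of which 2290 were among the 2374. Of 15 named genes that had not passed, 8 passed in that fit and 6 without control replicate 1. Of 85 named genes past the test, 54 kept their call with transcript length offsets and 73 with GC content and length offsets. With the latter the log2 fold changes of BHLHA15 (-2.04 to -1.24), CEBPB (-1.52 to -0.92), SREBF1 (-1.28 to -0.71) and ALDOA (-1.02 to -0.62) shrank. So did those of GDF15 (-1.17 to -0.64), PDGFRB (-0.90 to -0.57), RFC3 (0.85 to 0.56) and TAPBP (-0.58 to -0.34), which no longer passed. The share of higher calls was 42.8%, against 54.9% of 839 calls with offsets for transcript length and 95.2% of 3135 calls on log2(TPM + 1), where 2985 were higher and 150 lower around the median shift of 0.35.

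Lists of genes for proteins that bind and splice pre-mRNA were higher in the knockdown with the preset correlation. Of 14 genes for SR proteins and TRA2, which bind exonic enhancers, 6 rose and none fell (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.48 (camera adjusted p = 0.00152). SRSF7 rose from 38.6 ± 5.25 to 79.6 ± 8.57 CPM, TRA2B from 104.2 ± 11.8 to 211.5 ± 32.3, TRA2A from 19.97 ± 2.33 to 36.1 ± 2.82 and SRSF2 from 26.4 ± 0.85 to 40.1 ± 2.56. Of 19 genes for hnRNP proteins, which coat nascent transcripts, 5 rose (8 higher and 1 lower adjusted over the list alone), with a median of 0.54 (adjusted p = 0.00147). Without the 2 libraries that stood apart 9 of the 14 rose and none fell, and 14 of the 19 rose and 2 fell. In that fit 5247 of all 17583 tested genes passed. HNRNPA3 rose by 1.26, HNRNPA2B1 by 1.08, HNRNPH3 by 1.06, HNRNPA1 by 0.81 and HNRNPD by 0.79. Of 22 other core spliceosome genes 6 rose (6 adjusted over the list alone), with a median of 0.25 (adjusted p = 0.00895), among them PRPF4 (1.53) and PRPF3 (1.45) of the U4/U6 particle and SF3A2 (0.90) and SF1 (0.91) of branch point recognition. With an estimated correlation between genes the adjusted p was 0.286 for the SR and hnRNP lists and 0.299 for the core spliceosome list. Of 12 genes for second-step factors, SLU7 alone passed the test (1 lower adjusted over the list alone), and the list had a median of 0.16 (adjusted p = 0.707, and 0.962 with an estimated correlation). In the fit without the 2 libraries that stood apart, 3 of these 12 rose and 1 fell.

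The list of known targets of nonsense-mediated decay was also higher with the preset correlation. Of 23 such genes 6 rose (9 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 0.00264). Of 18 small nucleolar RNA host genes, whose spliced RNAs are degraded by the same pathway, 6 rose (9 adjusted over the list alone), with a median of 0.70 (adjusted p = 0.00152). ZFAS1 rose from 62.3 ± 8.50 to 145.0 ± 11.3 CPM, SNHG15 from 20.5 ± 0.80 to 44.0 ± 8.21, SNHG12 from 19.9 ± 2.75 to 38.4 ± 4.21 and SNHG5 from 46.0 ± 5.76 to 87.0 ± 13.98, all members of both lists, and SNHG17 rose by 1.20. TRA2A and SRSF2, counted above with the SR genes, are also members of the decay target list, so these lists are not independent. With an estimated correlation the adjusted p was 0.286 for the decay targets and 0.453 for the host genes. Of 17 genes for factors of nonsense-mediated decay 3 rose (3 adjusted over the list alone), among them SMG8 by 1.06 and UPF1 by 0.68, and the list itself did not pass (median 0.41, adjusted p = 0.0836, and 0.286 with an estimated correlation), although it did with GC content and length offsets (0.0206) and without control replicate 1 (0.0416). Leaving out the 2 libraries that stood apart, 8 of the 17 rose and 3 fell.

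The list of replication-dependent histone genes was lower with the preset correlation. Of 18 tested, 12 fell and none rose (15 and 0 adjusted over the list alone), with a median log2 fold change of -0.9988 (camera adjusted p = 2.64e-07, and adjusted p = 0.286 with an estimated correlation). H2BC21 fell from 103.9 ± 9.99 to 36.2 ± 1.82 CPM, H2AC6 from 90.5 ± 16.9 to 29.2 ± 1.88, H2BC8 from 164.5 ± 25.7 to 70.5 ± 9.84 and H2BC5 from 241.5 ± 25.5 to 129.3 ± 11.9, each uncertain as a single gene because histone copies share reads. Replication-dependent histone mRNAs typically end in a stem loop without a poly(A) tail. Whether the reads of these genes came from such mRNAs was not tested. A set of 183 small nuclear, small nucleolar and related RNAs, also without a tail, had a median of -0.84 in the same libraries. Of these, 3 passed the test as lower and 5 as higher. Tested as transcript classes, small nucleolar RNAs (camera adjusted p = 0.0718) and small nuclear RNAs (0.236) did not pass, and both were at 0.706 with an estimated correlation. Lists for cell division were higher with the preset correlation, although few members passed singly. Without the 2 libraries that stood apart 13 of 22 mitosis genes, 10 of 20 recombination genes, 10 of 24 replication genes and 7 of 16 cohesion genes passed as higher, and 1 replication gene as lower. In that fit, chosen after seeing the data, 5247 of all 17583 tested genes passed. Control replicate 1, left out there, had the highest control mean for mitosis genes (5.68 log2 CPM, against 5.24 and 5.48), so its removal favours a rise. Mitosis genes had a median of 0.44 (22 tested, 1 rose, TPX2 by 0.88, 0 adjusted over the list alone, adjusted p = 0.00144). Homologous recombination and R-loop genes had one of 0.36 (20 tested, 4 rose, 6 adjusted over the list alone, adjusted p = 0.00152), among them TOP1 at 0.99 and XRCC2 at 0.75. DNA replication genes had a median of 0.38 (24 tested, CDC6 and RFC3 rose by 1.02 and 0.85, 2 adjusted over the list alone, adjusted p = 0.00315). Sister chromatid cohesion genes had a median of 0.34 (16 tested, PDS5B and CDCA5 rose by 0.75 and 0.97, 2 adjusted over the list alone, adjusted p = 0.0146, and 0.0655 with GC content and length offsets). With an estimated correlation the adjusted p was 0.286 for mitosis, recombination and cohesion and 0.417 for replication. None of 12 genes of the DNA methylation machinery passed, also adjusted over the list alone (median 0.04, adjusted p = 0.690, and 0.889 with an estimated correlation), with TET3 at 0.41 and TET2 at 0.36, the latter at -0.21 with transcript length offsets. In the fit without the 2 libraries that stood apart, 2 of these 12 passed as higher and 1 as lower.

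Lists of sterol and lipid synthesis, glycolysis and stress response genes were lower with the preset correlation. Of 21 cholesterol and fatty acid synthesis genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.00315). FASN, the fatty acid synthase, fell from 255.3 ± 40.8 to 98.2 ± 17.2 CPM (log2 fold change -1.38), but stood at -0.44 with transcript length offsets (adjusted p = 0.239) and at -0.62 with GC content and length offsets (adjusted p = 0.0349). SREBF1, a transcription factor of the pathway, fell from 53.4 ± 12.3 to 22.0 ± 1.21 CPM. FDPS fell from 66.9 ± 7.59 to 32.5 ± 4.50, and CYP51A1 rose by 0.65. Of 18 hypoxia and glycolysis genes 5 fell (9 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.00152): EGLN3 at -1.62, ALDOA at -1.02, ADM at -0.995, HK1 at -0.96 and SLC2A1 at -0.69. Of 20 genes of the integrated stress response and unfolded protein response 7 fell and none rose (7 and 1 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.00645, and 0.0597 without knockdown replicate 1). CEBPB fell from 44.7 ± 1.71 to 15.5 ± 1.09 CPM, DDIT4 from 305.0 ± 88.5 to 108.2 ± 6.13, SEL1L from 162.9 ± 16.05 to 87.2 ± 13.2 and CHAC1 fell by 2.19. With an estimated correlation the adjusted p was 0.286 for the cholesterol and stress lists and 0.327 for hypoxia. The oxidative stress list did not pass (12 tested, median -0.14, adjusted p = 0.359, and 0.633 with an estimated correlation), with 1 gene lower (4 adjusted over the list alone).

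The inflammatory list was higher and the antigen presentation list lower with the preset correlation, although most members of either did not pass singly. Of 11 inflammatory and NF-kB targets 5 rose (7 adjusted over the list alone), with a median of 0.71 (camera adjusted p = 0.00147). CXCL8, a neutrophil chemokine, rose from 0.78 ± 0.41 to 7.34 ± 2.39 CPM, TNFAIP3, an inhibitor of NF-kB, from 9.75 ± 1.36 to 23.3 ± 7.43, BIRC3 from 5.38 ± 0.51 to 10.1 ± 0.61 and CXCL1 from 0.98 ± 0.17 to 2.94 ± 0.47, and CCL20 rose by 0.95. Of 15 antigen presentation genes 5 fell (5 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.00645, and 0.0655 with GC content and length offsets). Among them were PSMB10 at -1.58, HLA-E at -0.68, HLA-C at -0.59 and TAPBP at -0.58, the HLA genes being close paralogs, and HLA-C stood at 0.087 with GC content and length offsets. With an estimated correlation the adjusted p was 0.286 for both lists. The interferon response list had a median of -0.0069 over 16 genes (adjusted p = 0.972, and 0.972 with an estimated correlation), with 1 member higher, IRF1 at 1.14 (1 adjusted over the list alone). Of 15 TGF-beta and epithelial-mesenchymal genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.0678, 0.286 with an estimated correlation, and 0.0436 with GC content and length offsets). FN1, fibronectin, fell from 9882 ± 926 to 4371 ± 229 CPM, VIM (-1.22), THBS1 (-1.0006) and TGFBI (-0.65) fell too, and CCN1 rose by 0.92.

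Lists for the liver lineage and for cell death did not pass. Of 24 hepatocyte genes TTR, transthyretin, rose from 1.36 ± 0.23 to 4.03 ± 1.08 CPM, and MAT1A and ASGR1 fell (-1.35 and -1.12; 1 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.335, and 0.718 with an estimated correlation). Of 15 fetal liver and hepatocellular carcinoma genes 1 rose, and SOX9 and IGF2BP1 fell (-0.82 and -0.59; 1 and 3 adjusted over the list alone, median -0.04, adjusted p = 0.787, and 0.852 with an estimated correlation). IGF2BP1 stood at -0.33 with transcript length offsets and at -0.50 with GC content and length offsets. Of 16 DNA damage response genes PLK3 rose by 0.91 and GDF15 fell (-1.17; 1 and 1 adjusted over the list alone, median -0.19, adjusted p = 0.547, and 0.633 with an estimated correlation). No member of the apoptosis list passed, also adjusted over the list alone, and its 18 genes had a median of 0.08, a mean of -0.04 and an upward test (adjusted p = 0.928, and 0.962 with an estimated correlation), with BBC3 at -1.14. Apoptosis genes numbering 4 of the 18 passed as lower, and 0 as higher, without the 2 libraries that stood apart. None of 13 WNT and beta-catenin targets passed, also adjusted over the list alone, with a median of -0.0067, a mean of 0.03 and an upward test (adjusted p = 0.952, and 0.962 with an estimated correlation), ZNRF3 being at -0.44 and RNF43 at 0.30. Of 26 cytosolic ribosomal protein genes RPS14 alone rose, by 1.04 and by 0.25 with transcript length offsets (1 adjusted over the list alone, median -0.08, adjusted p = 0.978, and 0.987 with an estimated correlation). In the fit without the 2 libraries that stood apart, 5 of these 26 passed as higher and 3 as lower. The 15 mitochondrially encoded genes had a median of 0.45 with none past the test, also adjusted over the list alone (adjusted p = 0.0324, and 0.633 with an estimated correlation), MT-ND6 being at 0.85 and MT-RNR1 at 0.84. That list did not pass in the fits without control replicate 2, knockdown replicate 1 or knockdown replicate 3, nor with GC content and length offsets (0.273), with 1 surrogate variable (0.0676) or without the 2 libraries that stood apart (0.0983).

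Markers of other cell types were few. Of 4 immune markers tested PTPRC, the leukocyte antigen CD45, rose from 0.43 ± 0.07 to 1.78 ± 0.27 CPM, and LYZ, CD68 and CSF1R stood at -0.33, -0.18 and 0.05 (1 adjusted over the list alone, median -0.06, mean 0.39, camera adjusted p = 0.690 upward, and 0.753 with an estimated correlation). Of 2 fibroblast and stellate cell markers PDGFRB fell from 18.0 ± 4.59 to 9.64 ± 1.61 CPM, although on log2(TPM + 1) it stood at 0.40, 0.05 above the median shift, and COL1A2 was at -0.14 (1 adjusted over the list alone, list median -0.52, adjusted p = 0.3803, and 0.633 with an estimated correlation). Of 2 endothelial markers STAB2 was at 1.18 and PECAM1 at 0.25, neither past the test nor adjusted over the list alone (median 0.71, adjusted p = 0.359, and 0.602 with an estimated correlation). STAB2 stood at 0.34 with transcript length offsets, and at 0.29 on log2(TPM + 1), which is -0.067 relative to the median shift.

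Of the 31 lists 16 passed camera with the preset correlation, 11 upwards and 5 downwards, and 0 passed with an estimated correlation. The rotation test fry, which asks whether a list's genes move one way on balance, gave 15 lists. It did not pass DNA replication (adjusted p = 0.0575), small nucleolar RNA hosts (0.0876) and mitochondrially encoded genes (0.293), and it added decay factors (0.0241) and TGF-beta genes (0.0167). Relative to the median of all genes, the medians of the 16 lists kept their signs in every scaling tried that kept their genes. Every one of these lists was tested in libraries in which the mitochondrial ribosomal RNA share was higher, and the 7SL share lower, in all knockdowns than in all controls.

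**Figure D2:**
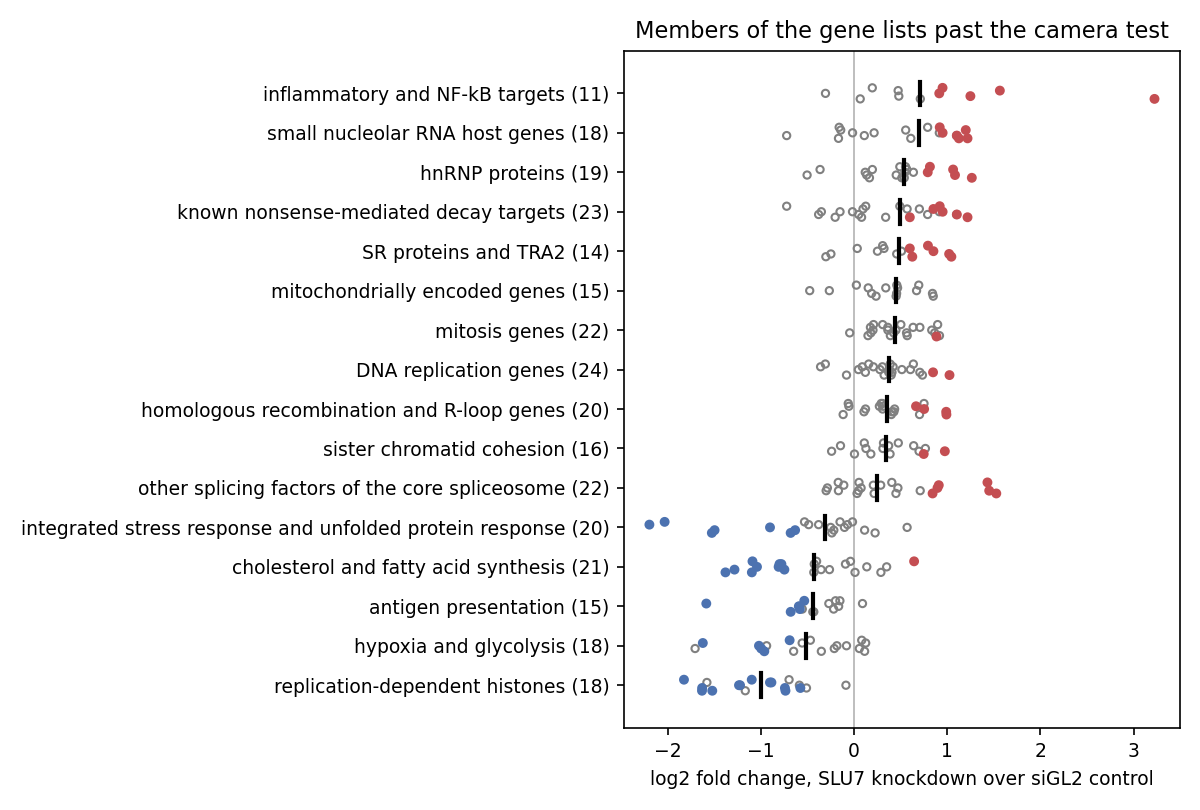
Log2 fold change, SLU7 knockdown over siGL2 control, of each tested member (horizontal axis) of the 16 gene lists past the camera test, with the number of members tested in parentheses. Filled points passed the edgeR test, red for higher and blue for lower, open points did not, and black bars are medians, from 0.71 for the inflammatory list to -0.9988 for the histones, and HLA-C among the blue points of antigen presentation stood at 0.087 with GC content and length offsets.

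For single transcripts, the direction differed by annotated class while no single transcript passed. Retained-intron transcripts, which keep an intron and are not annotated as coding, had a median log2 fold change of 0.35 over 7692 tested, and coding transcripts one of -0.20 over 22777. Against the other transcripts, the retained-intron class was higher (camera adjusted p = 3.80e-05, and adjusted p = 0.0202 with an estimated correlation) and the coding class lower (adjusted p = 0.000347, and 0.0136 with an estimated correlation). The decay class had a median of 0.10 over 3628 transcripts (adjusted p = 0.367, and 0.377 with an estimated correlation). The retained-intron and coding classes were the 2 of 12 past the test, and 4 passed without control replicate 1, without knockdown replicate 1 and without the 2 libraries that stood apart. SLU7-201 was at -1.32 (SE 0.28, edgeR adjusted p = 0.115), falling from 16.7 to 6.68 CPM on average. Of 43128 transcripts edgeR called 0 with the smallest adjusted p at 0.0994. At an unadjusted p under 0.05 there were 6959 (3241 higher, 3718 lower), where chance gives 2156. DESeq2 called 2812 (1115 higher, 1697 lower) and limma on log2(TPM + 1) 2437 (2116 higher, 321 lower, around a median of 0.28). In simulated libraries edgeR recovered 0 of 50 transcripts even at a 16-fold change and DESeq2 36 of 50, with 154 of its 207 calls false, so these data do not settle which transcripts changed.

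Within genes, a change in the mix of transcripts was called in 257 of 8869 genes with at least 2 tested transcripts (edgeR diffSpliceDGE, Simes adjusted p under 0.05). The 10 genes with the smallest p were DDX5 and RBM39, which act in RNA processing, SUN1 of the nuclear envelope, the acetyltransferase KAT6A, ZNF644, the chaperone HSPA8, SRP68 of the signal recognition particle, the urea cycle enzyme CPS1, the cohesin subunit SMC1A and SNX17. The coding transcript ENST00000533540.5 of HSPA8 made up 15.4% ± 5.26 of the TPM of its gene in controls and 0.45% ± 0.78 in knockdowns, and HSPA8-224 0.01% ± 0.02 and 7.63% ± 1.20. The retained-intron transcript SNX17-207 went from 19.3% ± 3.78 to 35.3% ± 0.58 (unadjusted p = 0.0730) and the coding transcript SRP68-202 from 18.7% ± 2.03 to 1.98e-07%. The coding transcript KAT6A-214 held 19.9% ± 3.10 in controls and 0.0017% ± 0.0029 in knockdowns, and SMC1A-208 4.4e-06% and 3.58% ± 1.99. DDX5-203, a decay transcript, held 8.86% ± 5.21 in controls and 1.23e-05% in knockdowns, while SUN1-205 held 4.55% ± 1.72 and SNX17-203 10.0% ± 3.70 in controls and both were assigned 0 in every knockdown. Near-identical transcripts of a gene compete for the same reads, and a share of about 0 is an estimate of that assignment. Limma called 259 genes, of which 33 were shared, where independent lists would share 7.51. In simulated libraries 24 of the 26 usage calls of edgeR were false and 2 of 50 changes of 16-fold were found, so single genes in this group are uncertain. The count was 808 without control replicate 1, 156 without knockdown replicate 2 and 865 without the 2 libraries that stood apart. Among splits of the 6 libraries, 3 against 3, that mixed the groups, the highest count was 180.

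Summed over annotated classes, retained-intron transcripts gained share within their genes. Their class rose relative to the rest of the gene in 60 of 4270 coding genes and fell in 0 (edgeR diffSpliceDGE, adjusted p under 0.05), with a median relative log2 change of 0.36 and 75.9% of genes above 0. The gain was not confined to them. The class of other transcripts, neither coding, retained-intron nor decay, rose in 21 of 2975 genes and fell in 8. Its median was 0.17, with 62.7% of genes above 0. In EIF4G1, the scaffold of translation initiation, retained-intron transcripts went from 6.06% ± 1.03 to 24.2% ± 3.86 of the TPM of the gene (n = 3, relative log2 change 2.56, SE 0.26, adjusted p = 0.000132). In KIAA0100 they went from 9.78% ± 1.22 to 45.2% ± 3.94. In RACK1, a ribosome-bound scaffold, they went from 3.12% ± 0.90 to 14.4% ± 3.10, in the elongation factor gene EEF1G from 2.11% ± 1.03 to 14.97% ± 4.85. In the ribosomal protein gene RPL5 they went from 3.53% ± 1.75 to 21.2% ± 15.03, in the histone chaperone gene SSRP1 from 0.70% ± 0.22 to 3.83% ± 0.87 and in NONO, a nuclear RNA-binding protein gene, from 1.43% ± 0.42 to 5.28% ± 1.37. KIAA0100 also fell as a gene (-0.83), and the other 6 named here did not pass the gene test. The leading retained-intron transcript of EIF4G1, EIF4G1-232 (chromosome 3, 184325299 to 184326908, plus strand, GRCh38), spans intron 20 of the 33 introns of EIF4G1-205 (184325374 to 184325479). That of RACK1, RACK1-230, spans intron 2 of 8 of RACK1-228 on chromosome 5 (181241564 to 181242173, minus strand), and that of EEF1G, EEF1G-203, intron 1 of 9 of EEF1G-201 on chromosome 11 (62572743 to 62573830, minus strand), with the coding transcripts chosen after the values were seen. That of SSRP1, SSRP1-202, spans 6 of the 16 introns of SSRP1-201. Those of KIAA0100 (KIAA0100-207, 446 bases) and RPL5 (RPL5-210, 591 bases) span no whole intron of a coding transcript of their gene. The test used counts, while TPM also depends on the effective length of each transcript. Annotated length exceeded it by a median of 141.6, 125.5 and 121.1 bases in the controls and 141.5, 146.7 and 149.996 in the knockdowns. With the effective length averaged over the libraries, an alternative chosen after seeing the data, the shares were 6.14% and 24.0% in EIF4G1 and 9.78% and 45.2% in KIAA0100. In simulated libraries the test made 36 calls on retained-intron classes, of which 0 were false. It found 6 of 50 changes of 4-fold and 30 of 50 of 16-fold. Classes were drawn independently there, without reads split between transcripts and without libraries that stand apart. That simulation thus gives no error rate for the 60 calls above. The count was 155 without control replicate 1 (144 higher, 11 lower), 13 without control replicate 2 or 3, 11, 7 and 20 without knockdown replicates 1, 2 and 3, and 189 without the 2 libraries that stood apart (177 higher, 12 lower).

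**Figure D3:**
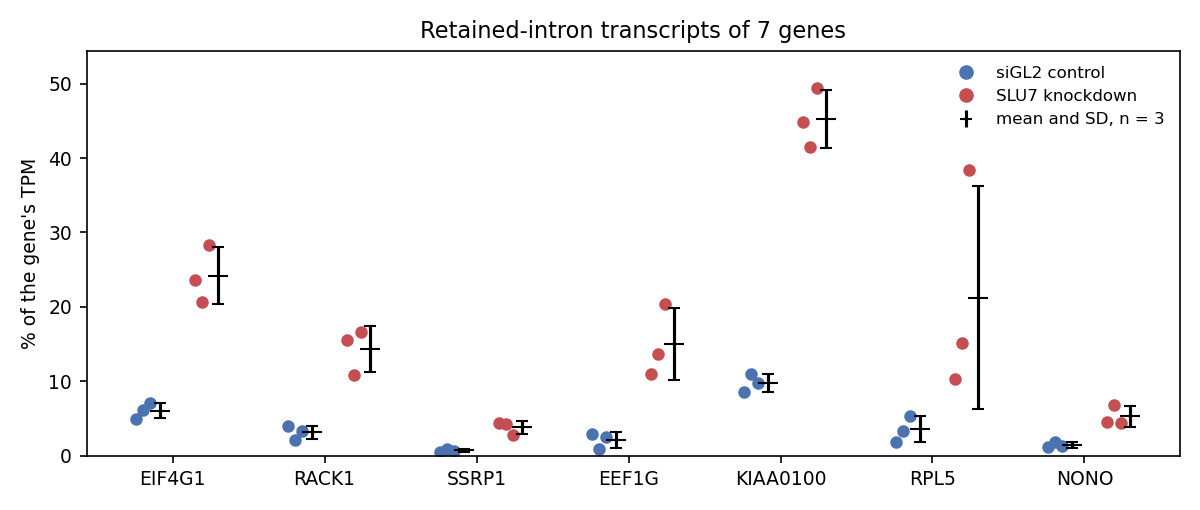
Share of the TPM of each gene held by its retained-intron transcripts, in percent (vertical axis), for 7 of the genes with the smallest p (horizontal axis). Points are the 6 libraries and black marks the mean and SD of 3, as for EIF4G1 with 6.06% in controls and 24.2% in knockdowns.

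The decay class moved both ways, with 30 genes higher and 25 lower of 2704 and a median relative log2 change of 0.07. In EIF4G1 it went from 3.25% ± 0.99 to 8.38% ± 0.93 of the TPM of the gene, in IGF2R, the mannose 6-phosphate receptor, from 7.44% ± 0.43 to 24.4% ± 6.02 and in AMPD2 from 8.13% ± 2.64 to 15.8% ± 2.19. In VCP, a segregase of ubiquitinated proteins, it went the other way, from 43.4% ± 15.8 to 15.1% ± 3.51, and in NCL, nucleolin, from 7.49% ± 6.95 to 0.07% ± 0.13. It also rose in HSP90AA1 (1.08% to 5.42%), TMED10 (0.12% to 6.09%), ZNF75A, NCAPG2 and RFC4 (4.73%, 4.70% and 6.98% in knockdowns, all below 0.01% in each control), and fell in RNF130 and POLR2J3, the latter one of several close copies, from 21.8% ± 8.46 and 23.7% ± 12.4 to 0. The 55 calls became 150 without control replicate 1, 21 and 24 without control replicates 2 and 3, 27, 11 and 36 without knockdown replicates 1, 2 and 3 and 166 without the 2 libraries that stood apart. The balance changed between fits, from 88 higher and 40 lower with 1 surrogate variable and 61 and 36 with limma to 10 and 17 without knockdown replicate 1.

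Over whole libraries, retained-intron transcripts of coding genes held 14.8%, 13.7% and 14.3% of the TPM of those genes in the controls and 17.7%, 17.7% and 17.6% in the knockdowns, a difference of 3.45 percentage points, and of 3.38 with averaged effective lengths (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 allows). Coding transcripts of the same genes held 65.9% ± 1.35 and 61.1% ± 0.75 (exact p = 0.1), and decay transcripts 7.43% ± 0.36 and 7.69% ± 0.37 (exact p = 0.5). Transcripts annotated as processed also rose, from 12.4% ± 0.46 in controls to 13.5% ± 0.46 in knockdowns (exact p = 0.1). Over the TPM of all transcripts, where 7SL RNA alone took between 30.8% and 51.7%, the retained-intron share was 2.59% ± 0.73 and 4.39% ± 0.52 (exact p = 0.1), and the decay share 1.35% ± 0.39 and 1.91% ± 0.32 (exact p = 0.2). The coding share was 11.7% ± 2.65 and 14.9% ± 1.72 (exact p = 0.3), the opposite direction to that within coding genes and to the share of estimated counts, 39.3% ± 0.61 and 36.5% ± 1.12 (exact p = 0.1).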

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

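The gene comparison called 2374 genes, and between 1867 and 3196 with RLE size factors, other filters, DESeq2, log2(TPM + 1), GC content offsets or without structural RNA. The stricter filter tested 17141 genes, more than the 17109 of the standard one. It called 36 with glmTreat against a 1.5-fold change, which asks for more than any change, 839 with transcript length offsets, and between 0 (without knockdown replicate 2, where 4244 had an unadjusted p under 0.05) and 4455 (without control replicate 1) with 1 library left out. Of 85 named genes past the test, 81 kept their call with DESeq2 and 57 on log2(TPM + 1). Alternatives chosen after seeing the data gave 5247 without the 2 libraries that stood apart and 5176 with 1 surrogate variable. With the replicate block, edgeR called 0 genes (4210 at an unadjusted p under 0.05), 87 genes for transcript usage, 4 for the retained-intron class and 7 for the decay class, and SLU7 stood at -1.004. Same-numbered libraries had deviations correlated at -0.41, 0.11 and -0.37, and not every library correlated best with its own number, which shows no pairing by number. A smaller effect shared by number cannot be excluded, because the 2 libraries that stood apart dominate these deviations. SLU7 ranged from -1.09 to -0.92 with 1 library left out, and was -1.002 with glmTreat, -0.57 with length offsets and -0.063 on log2(TPM + 1). Transcript calls rose from 0 to 94 without a filter, 2812 with DESeq2 and 2437 on log2(TPM + 1). Transcript usage gave 156 to 808 genes with 1 library left out, 865 without the 2 libraries and 442 with the gene-level test. The retained-intron class gave 36 without a filter, 7 to 155 with 1 library left out, 189 without the 2 libraries, 246 with 1 surrogate variable and 282 with limma diffSplice. The decay class gave 11 to 150 with 1 library left out, 166, 128 and 97 in the last 3 of these. The coding share difference was 3.24 percentage points of all TPM, and ran from 1.91 to 4.56 with 1 library left out. It reversed to -2.78 as a share of estimated counts and to -4.81 within coding genes, where the retained-intron difference moved to 3.45.

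Camera passed 2 transcript classes, 2 to 4 with 1 library left out and 4 without the 2 libraries. The direction of classes and lists far from the threshold turned in some fits: misc_RNA (adjusted p 0.767 to 0.988 with 1 library left out) and unprocessed pseudogenes (0.993 without the 2 libraries). With 1 library left out, the adjusted p ran from 0.246 to 0.972 for second step factors and DNA methylation, 0.859 to 0.972 for interferon, 0.739 to 0.960 for apoptosis, 0.723 to 0.980 for WNT targets and 0.604 to 0.992 for ribosomal proteins. Without the 2 libraries it was 0.792 for interferon, WNT targets and ribosomal proteins and 0.920 for apoptosis. Without a filter it was 0.869 for apoptosis, 0.718 for WNT targets and 0.798 for endothelial markers. It was 0.944 for DNA methylation and 0.970 for interferon with 1 surrogate variable, 0.688 for immune markers without structural RNA and 0.959 for interferon with GC content offsets. The number of lists past camera fell from 16 to 0 with an estimated correlation. Single genes reversed on log2(TPM + 1), where the median gene stood at 0.35: IGF2BP1 0.15, FASN 0.061, ZNRF3 0.00022, PDGFRB 0.40, HNF4A 0.026 and DNMT1 0.31. Relative to that median, PDGFRB alone of these turned (0.05), as did STAB2 (-0.067), and the others stood at -0.20, -0.29, -0.35, -0.33 and -0.045 in the same order. TET2 reversed to -0.21 with length offsets, HLA-C to 0.087 and ALB to -0.027 with GC content offsets, and DNMT1 to 0.051 without the 2 libraries, with a range of -0.36 to 0.15 when 1 library was left out. The usage change of CPS1-212 was -0.039 with limma and ran from -5.84 to 2.53 with 1 library left out. For these changes the cause was not tested. Of the tested transcripts 22.9% had a library with a count of 0, which limits the transcript results, and its cause was not tested.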

Other observations

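Gene families were grouped by the first letters of their symbols after the data were seen, 81 families of at least 15 tested genes. Solute carriers (SLC) leaned downwards, with 56 of 243 lower and 2 higher (edgeR), a median log2 fold change of -0.47 (camera adjusted p = 3.23e-08, and 0.685 with an estimated correlation), and -0.29 on log2(TPM + 1) relative to the median gene. The glutamine transporter SLC1A5 fell from 127 to 44.7 CPM and the glucose transporter SLC2A3 from 1558 to 473 CPM. Zinc finger genes (ZNF) leaned upwards, with 46 of 435 higher and 5 lower and a median of 0.36 (adjusted p = 1.07e-06, and 0.685 with an estimated correlation), ZNF335 rising from 42.1 to 98.0 CPM. DEAD-box helicases (DDX) did too, with 6 of 34 higher and 0 lower and a median of 0.31 (adjusted p = 0.0134, and 0.763 with an estimated correlation), DDX55 rising from 18.6 to 50.5 CPM. With GC content and length offsets 4 DDX genes were higher and 1 lower. On log2(TPM + 1), relative to the median gene, the ZNF median was 0.22 and the DDX median 0.51.

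The deviations of control replicate 1 and knockdown replicate 3 from their groups correlated at 0.44. GC content or transcript length bias was tested as a cause as foreseen, and an exchange of their labels was tested only after the pattern was seen. With GC content and length offsets the correlation was 0.431, which argues against that bias as its source. SLU7 was 1.99 times higher in control replicate 1 than in knockdown replicate 3 (20.7 and 10.4 CPM), which argues against exchanged labels. The cause stayed open.

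For the gain of retained-intron transcripts, lower count totals and transcript length were foreseen as explanations, and nuclear RNA was tested only after the result was seen. With every library thinned to 5190940 counts the median relative change was 0.369, against 0.362 before, and 62 of 3882 classes were called, all higher. The lower count totals of the knockdowns are thus not a likely source. Retained-intron transcripts changed by 0.409 more than transcripts of other classes with matched length. The SE of 0.014 comes from resampling transcripts and leaves out the spread between libraries. Each change was taken relative to the rest of its gene, so a gain of retained-intron transcripts lowers the values of the others. The difference may thus be partly built in and cannot alone decide whether short transcripts gained whatever their class. By class, those of matched length had medians of 0.21 for processed transcripts, beside 0.41 for retained-intron ones, and -0.04 for coding ones. The class of other transcripts also rose relative to the rest of its genes (median 0.17, 21 genes higher and 8 lower of 2975). Part of the gain might thus be shared with short non-coding transcripts, and this stayed open. More nuclear RNA in the knockdowns might raise intron-bearing RNA. The 7 nuclear long non-coding RNAs tested had a median of -0.14 (SE 0.27 over RNAs), with 0 higher and 1 lower, too wide a spread to decide.

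For the fall of histone genes, redistribution between copies and a general fall of intronless genes were foreseen, and poly(A) recovery and S phase were tested only after the result was seen. Reads moved between copies would leave the sum unchanged, but the CPM summed over 132 histone genes changed by -0.73 (SE 0.026 over libraries). Single-exon genes other than histones stood 0.12 (SE 0.063 over genes) above multi-exon genes. Neither explanation is thus a likely source, although an SE over genes leaves out the spread between libraries. DNA replication genes did not fall, with a median of 0.38 (SE 0.057 over genes). Only 2 of the 24 passed singly, and with an estimated correlation the camera adjusted p was 0.417. Levels of these mRNAs need not follow the number of cells in S phase, so this test cannot decide whether fewer cells were in it. A candidate explanation is lower recovery of RNAs without a poly(A) tail in the knockdown libraries. There, 183 such RNAs had a median of -0.84 (SE 0.08 over RNAs) beside -0.9988 for the histones. Singly, 5 of these RNAs passed as higher and 3 as lower, and neither small nucleolar nor small nuclear RNAs passed as a class (camera adjusted p = 0.0718 and 0.236). That test does not separate a difference in library preparation from an effect of SLU7 on such RNAs. Nor was it tested whether the histone reads came from mRNAs without a tail.

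The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. Counting the real split among them, 1 called at least as many genes as the real 2374 (highest other 1), and 10 at least as many transcripts as the real 0 (highest other 0). In the same way, 1 called at least as many usage genes as the real 257 (highest other 180) and 1 at least as many retained-intron classes as the real 60 (highest other 2).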
